A study of Homo sapiens with 2 samples.

How the data were processed

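Cells of the human promyelocytic leukaemia line HL-60 were profiled by droplet single-cell RNA sequencing with a 3′ kit (version 3.1 chemistry) in 1 pool that combined 6 hashtagged groups. Hashtags are barcoded antibodies, here against CD298 and beta2 microglobulin, which mark every cell of a culture before cultures are mixed. The pool gave 2 libraries, 1 of mRNA-derived cDNA and 1 of hashtag-derived cDNA, sequenced at 4 parts to 1 per the labels' protocols. The submitters' processing notes name Cell Ranger 6.0.0, Seurat 4.2.1 and the human build GRCh38. They state neither the role nor the order of the tools.

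The values analysed here are 2 text lists: the cell barcodes and the features of a filtered matrix. Both hold identifiers as deposited by the authors, and neither holds a measured quantity. The counts that link barcodes to features were not analysed here. The depth per cell, the hashtag assigned to each cell and the level of each gene are therefore unknown. The 9 planned comparisons between hashtag groups were fixed before the data were examined and could not be made. They would have had 1 hashtagged sample per group and no replicates.

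Lines of each list were counted, all and distinct. Features were split by the type given in the list, and the 6 hashtag features were matched to the groups in the labels by their tag number. The 19 gene lists fixed before the data were examined were matched to the features by exact symbol. The rule for named genes needed expression values and named none, so the genes named below were chosen from the lists of identifiers alone, after these were seen. Feature identifiers were looked up in a separate table of Ensembl identifiers and symbols. Of 36601 gene identifiers, 36366 (99.4%) were in that table, with the same symbol for 23414. For 11045 of the 12952 with another entry, the table gave no symbol other than the identifier.

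Barcode base composition was computed over all 16 positions, counted from 1 at the 5′ end. Shares carry exact Clopper-Pearson 95% intervals, which treat bases or barcodes as independent and cover counting error only. Barcodes with another barcode at 1 or 2 changed bases were counted and set against 20 random lists of the same size. The count of barcode partners and of 1-base neighbours was tested on simulated data, where 300 of 300 planted pairs of each kind were recovered in a list of 22415 random barcodes. The random barcodes lacked the structure of the real list, so this checks the counting step alone. Computations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. Alternatives were distinct entries, distinct names, another way of matching symbols, and the upper and lower parts of the barcode list taken separately.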

Results

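The series was designed to compare wild-type HL-60 cells with an HL-60 line carrying the F508del change of CFTR, the chloride channel gene mutated in cystic fibrosis (CF). HL-60 is a human promyelocytic leukaemia line that differentiates into neutrophil-like cells when dimethyl sulfoxide (DMSO) is added. Each of the 2 genotypes was sampled in 3 states, which makes 6 groups: parental cells, cells differentiated with 1.25% DMSO for 5 days, and differentiated cells exposed to 42.67 µg/ml of Pseudomonas aeruginosa lipopolysaccharide (LPS) for 16 hours. All groups were read in 1 pool and told apart by hashtag, so each group was 1 sample with no replicate.

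The filtered barcode list held 22415 cell barcodes, all distinct and all with the same well suffix. The list does not say which group a barcode belongs to. The number of cells per group, the share of doublets and the depth per cell were not analysed here.

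The feature list held 36607 entries, of which 36601 were genes and 6 were hashtags. The tags of all 6 hashtag features matched the labels. B0251 marked wild-type parental cells, B0252 wild-type differentiated cells and B0253 wild-type differentiated cells with LPS. B0254, B0255 and B0256 marked the same states of the CF line in that order. The feature identifiers give the differentiated groups by their DMSO treatment.

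The design implies 3 comparisons of CF with wild type, 1 in each state. It also implies 2 comparisons of differentiated with parental cells and 2 of LPS with no LPS, 1 per genotype in each case. A further 2 would compare these changes between genotypes, without a test. None of these 9 comparisons could be made from identifiers alone. No gene, gene group or cell type can be called higher or lower in any group here.

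What the feature list covers can be stated. It holds 36601 genes, so full coverage of lists of well-known genes describes that list and not this experiment. All 243 genes of the 19 lists fixed in advance were features. They included 12 azurophil granule genes such as MPO and ELANE, which encode myeloperoxidase and neutrophil elastase, and 12 genes of specific and tertiary granules such as LTF (lactoferrin) and MMP9. They also included 16 surface and receptor genes of mature neutrophils such as CSF3R and FPR1, and 6 genes of the NADPH oxidase, the enzyme of the respiratory burst. The 20 genes of the NF-κB and LPS response, such as IL1B and CXCL8, the 18 interferon response genes and the 20 cell cycle genes were all listed. Presence in the list says that reads could be assigned to a gene, not that the gene was expressed.

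CFTR was a feature under the identifier ENSG00000001626, and the RefSeq annotation of GRCh38 places it on chromosome 7 from 117480025 to 117668665. Of 10 pairs of a listed gene and a similar copy, both members were features in 8. These included FCGR3B, the neutrophil Fc receptor gene on chromosome 1 from 161623196 to 161631963, and FCGR3A on the same chromosome from 161541759 to 161550737. NCF1, an NADPH oxidase subunit gene on chromosome 7 from 74774011 to 74789315, was a feature, whereas its copies NCF1B and NCF1C were not listed under those symbols. Counts of such genes would be uncertain where reads fit more than 1 copy.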

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

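Counting distinct entries left the number of barcodes at 22415 and the number of features at 36607. Counting features by distinct name gave 36597, because 10 symbols, such as MATR3 and TBCE, each stood for 2 gene identifiers. Matching the gene lists without regard to case or version found the same 243 genes. Matching by Ensembl identifier, an alternative chosen after seeing the data, found 242. The missing gene was SOD2, for which the name table gave no identifier found in the feature list. GC content over all barcode bases was 49.7% (95% interval 49.6% to 49.9%). The interval treats bases as independent, although the base at position 8 fixed the base at position 9. GC content was 49.7% in the upper part of the evenly divided, sorted list and 49.8% in the lower part. That split follows the alphabetical order of the barcodes and is not a processing choice. The settings fixed in advance for the 9 comparisons between groups and for cells per hashtag were not run, since these need counts. No paired analysis was possible, because no counts were analysed and no comparison was made. Each group is 1 hashtagged sample.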

Other observations

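The barcodes used only 4 of 16 possible base pairs at positions 8 and 9. A was always followed by G (5301 barcodes), C by A (5713), G by T (5738) and T by C (5663). Each other pair of adjacent positions held all 16. This was noticed in the base composition and not planned. GC content by position ran from 47.5% at position 7 to 51.6% at position 13.

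A list of 22415 barcodes from 1 well may hold cells counted more than once, and 2 technical routes to this were set out before their results were seen. The first rests on background knowledge of this chemistry that the labels do not state: each bead carries a second capture sequence for antibody tags, under a barcode with complemented bases at positions 8 and 9. If that holds and beads were counted under both barcodes, over 10% of barcodes should have such a partner in the list, against under 1% if not. The share was 0.0981% (22 barcodes, 95% interval 0.0615% to 0.149%), against 12 to 42 barcodes when each of the 12 adjacent position pairs that leave out positions 8 and 9 was complemented. The pairs 7 with 8 and 9 with 10 gave 0, which the rule at positions 8 and 9 fixes in advance. Under that description of the beads, the share lies below the 1% bound, so few entries of the list can be the same bead listed under both barcodes. This concerns the list alone: software that merged the barcodes before listing cells would fix the same low share in advance. Since the submitters' notes do not state the role of each tool, whether this happened is unknown. The share therefore does not show how beads were read before the list was made. For sequencing errors that split cells, the share of barcodes 1 base from another was 0 of 22415, with an upper limit of 0.0165%. The list thus held no pair of barcodes that a 1-base error could have made. Whether such errors occurred is not decided by this test, on a comparison chosen after its result was seen. The 20 random lists with the same rule at positions 8 and 9 held 4 to 32 such barcodes. A list that lacks even the neighbours of random sequences cannot show whether such errors occurred before it was made. Barcodes with another at 2 changed bases numbered 4184 in the real list and 328 to 427 in the random ones. The random lists were drawn from all sequences under that rule. The barcodes that the kit allows were not examined, so the reason for the excess at 2 bases is unknown. Splitting of cells at that distance was not tested. Doublets and cell-free droplets stay open, because both need counts. No biological explanation was tested.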
